A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

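Transcripts were measured on 12 Affymetrix Yeast S98 arrays, 3 for each combination of strain (wild type MLY61 or gpa2 deletion MLY132, both diploid and homozygous for ura3-52) and medium (YPM or SLAM). Per the labels' protocols, cells were grown in YPM to an OD600 of 1.0, and about 200 OD600 units were collected by filtering or moved to SLAM, which holds 50 µM ammonium sulfate, 2% maltose and 0.17% yeast nitrogen base, for 2 h at 30 °C. RNA was kept in RNAlater, purified with RiboPure, amplified from a poly-T primer with a T7 promoter and labelled with biotin, per the same protocols. Each group came from 3 cultures, per the design text. The media differ in more than nitrogen, since 1 is rich and the other defined.

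The deposited table held log2 expression values for 9335 probe sets on 12 columns, all of which were used, with no missing value. The submitters' processing notes name GCOS 1.2, MAS5 and RMA without saying which of them made the deposited log2 values, and no detection calls were given in the sources used here. The medians of the arrays lay between 7.34 and 7.51, and no further normalization was applied. The 60 control probe sets were left out. The annotation gave 1 gene symbol for 6504 probe sets, several for 328 and none for 2443; the last 2 kinds were left out of the gene tests because they name no single gene. Where a gene had more than 1 probe set (315 genes), the one with the highest mean was kept, which left 5656 genes, 300 of them on probe sets that can share targets. All 6504 gene IDs were found in the yeast gene table of assembly R64, and 0 symbols were updated.

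A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (8 residual degrees of freedom, prior degrees of freedom 4.11, prior variance 0.114). The 5 comparisons were SLAM against YPM in each strain, deletion against wild type in each medium, and the difference between the strains' SLAM responses. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene passed at adjusted p < 0.05. Errors are standard errors of the log2 difference unless marked SD. The median standard error was 0.29 on the log2 scale, or 0.41 for the difference of responses; 3 arrays a group limit the precision. Where a gene's lower group averaged no more than 5.60, the highest GPA2 reading of the deletion strain, its change is a lower bound. Among named list members this held in the wild type for ATG40, RGS2, PHM8, PHM6, FUS1 and COX2. It held in the deletion strain for ATG40, UTP13, PXA1, TPK3, ADE4, SPL2 and SMK1, and between strains in SLAM for RGS2 and ATG4. The median log2 change over all genes was -0.05, 0.01, -0.07, -0.03 and 0.04 in the 5 comparisons. The 3 values of a group did not overlap those of the other in 2010, 2521, 1088 and 1211 genes (35.5%, 44.6%, 19.2% and 21.4%) in the first 4 comparisons, where chance alone gives 10%.

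From 40 gene lists, written from general knowledge, 39 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the residuals, and fry, were run beside it. Camera at the preset correlation called 12 lists higher and 7 lower, 12 and 9, 12 and 4, 9 and 8, and 6 and 7 in the 5 comparisons; fry called 7 and 7, 10 and 7, 0 and 0, 3 and 5, and 0 and 0; with an estimated correlation none was called, the smallest adjusted p being 0.411, 0.274, 0.0850, 0.349 and 0.290. For each list, members passing over all genes and members passing when adjusted over the list alone were counted. DUR1,2, TDH2, 6 histone genes and some genes of other lists had no probe set of their own and were not analysed here.

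Genes were named by a rule. In each comparison the 10 largest rises and 10 largest falls were named among genes that passed and whose groups did not overlap; for the difference of responses only adjusted p counted. GPA2, URA3 and FLO11 were named in every comparison. For each list described, up to 4 of the largest passing members were named, or the 2 members with the smallest p where none passed. TSL1, the gene with the smallest adjusted p in the last comparison (GTO1), the genes of 3 sets added later and the genes that passed under a single alternative only were named after their values were seen.

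Groups, comparisons, thresholds, lists, the naming rule and most alternatives were chosen before the data were examined. Those alternatives were a floor at the 10th percentile (log2 4.31), quantile normalization, median centring, leaving out the dimmest genes (3770 kept), all 9275 probe sets, only the 6 arrays of a comparison, a variance trend with robust moderation, a 2-fold filter, adjusted p < 0.01 and each array left out in turn; for lists, an estimated correlation, fry, quantile normalization and leaving out probe sets that can share targets. Leaving out both arrays that stood apart, leaving out each of them or deletion SLAM replicate 2 alone for the lists, and array weights were chosen after seeing the data. Array weights used limma's gene-by-gene method, because the default method gave a convergence warning. GPA2 in all arrays was compared between strains by an exact permutation test. Correlations between arrays were Spearman's.

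The fit was tested on simulated data with 200 of 5656 genes changed. It recovered 35%, 39%, 45%, 42% and 9% of genes changed by log2 1 in the 5 comparisons and 86%, 87%, 85%, 86% and 55% of those changed by log2 2. The share of false calls was 4.72%, 4.55%, 9.09%, 6.57% and 3.03%, above the nominal 5% for both strain comparisons. Each share came from 1 simulated data set, and all comparisons of 2 groups were simulated alike. Differences among those shares therefore come from the random draw and describe no single comparison. A list moved as a whole was called, and 0 of 39 lists left unmoved were. Simulated genes were independent of each other, with the same SD in all groups. The simulation therefore could not show false list calls that come from correlated genes. Replicate numbers were given here in the order of the samples and were not used to pair cultures. Whether a YPM and a SLAM sample shared a starter culture is not given in the sources used here, and no fit with pairs was run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Proteins named in the series title were not analysed here.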

Results

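Yeast transcripts were measured on 12 Affymetrix Yeast S98 arrays from diploid Saccharomyces cerevisiae, 3 per group. The wild-type strain MLY61 and the gpa2 deletion strain MLY132 were each sampled in YPM, a rich maltose medium, and after 2 h in SLAM, a low-ammonium maltose medium that the labels call pseudohyphal-inducing. After control probe sets and probe sets without 1 gene symbol were left aside, 5656 genes were tested. The comparisons asked how each strain's transcripts differed between the 2 media, how the strains differed within each medium, and whether the response to SLAM differed between strains.

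GPA2, which encodes a G protein alpha subunit acting upstream of cAMP signalling, was low on every deletion array and high on every wild-type array. Its log2 expression averaged 5.39 ± 0.18 (SD, n = 6) in the deletion strain and 10.44 ± 0.55 (n = 6) in the wild type, a difference of -5.05 (exact two-sided permutation p = 0.00216 over 924 splits, the smallest possible). In YPM the deletion arrays read 5.60, 5.20 and 5.48 and the wild-type arrays 10.27, 9.70 and 10.00. In SLAM the deletion arrays read 5.42, 5.14 and 5.49 and the wild-type arrays 11.10, 10.999 and 10.56. The strain difference was at least 23.7-fold in YPM (log2 -4.57, SE 0.23, adjusted p = 7.04e-07) and at least 46.4-fold in SLAM (log2 -5.53, adjusted p = 7.23e-08). GPA2 itself rose in wild-type cells in SLAM by log2 0.89 (SE 0.23, n = 3 per group, adjusted p = 0.0302). The remaining signal in the deletion strain lay at the 6.63 percentile of all genes, so these folds are distances to a background reading and not comparable between media. URA3, which both strains carry in the ura3-52 form, read 5.12 in wild-type and 4.73 in deletion cells in YPM, with no call in any comparison. In SLAM it read 4.77 and 4.33. These means all lay under the highest GPA2 reading of the deletion strain (5.60), so URA3 differences on this probe set were taken as between background readings. That level comes from a different probe set. A URA3 control probe set, left out of the tests with the other controls, read from 5.11 to 6.40 across the arrays.

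**Figure D1:**
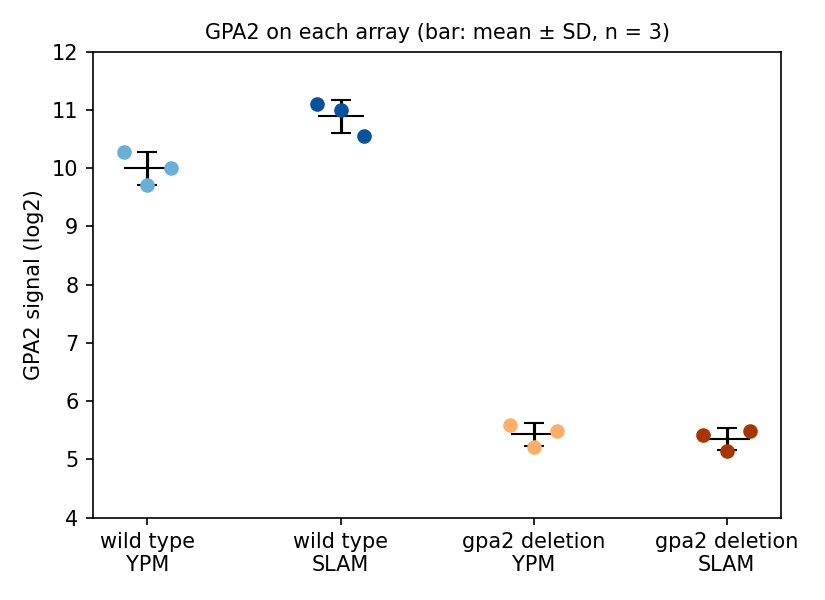
GPA2 log2 expression in each of the 12 arrays by strain and medium. Points are arrays and bars are group means with SD, n = 3 per group.

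The first principal component, with 59.4% of the variance, ran mostly from YPM to SLAM arrays, and the second held 11.1%. All 3 deletion SLAM arrays lay at 42.8 to 54.9 on the first component, wild-type SLAM replicates 1 and 3 at 19.4 and 28.4, and wild-type SLAM replicate 2 at -10.8. In wild-type SLAM replicate 2 the nitrogen catabolite repression targets averaged 0.77 above the wild-type YPM mean, against 2.24 and 2.80 in replicates 1 and 3, and the sulfate assimilation and methionine synthesis genes averaged 2.62, against 0.32 and 1.34. The deletion SLAM replicate 2 shared the latter trait, with 2.70 against 0.85 and -0.31 in the other deletion SLAM arrays. The deletion YPM replicate 3 lay at -6.17, against -27.3 and -34.5 for its group. Its iron uptake genes averaged -2.47 from the wild-type YPM mean, where the other 2 deletion YPM arrays had 0.35 and 0.52, and its gluconeogenesis and glyoxylate cycle genes averaged 1.33, against -0.11 and -0.30. Spearman correlations ranged from 0.867 to 0.984 within groups and from 0.711 to 0.978 between groups. The median gene SD was 0.208 in wild-type YPM, 0.387 in wild-type SLAM, 0.227 in deletion YPM and 0.340 in deletion SLAM.

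**Figure D2:**
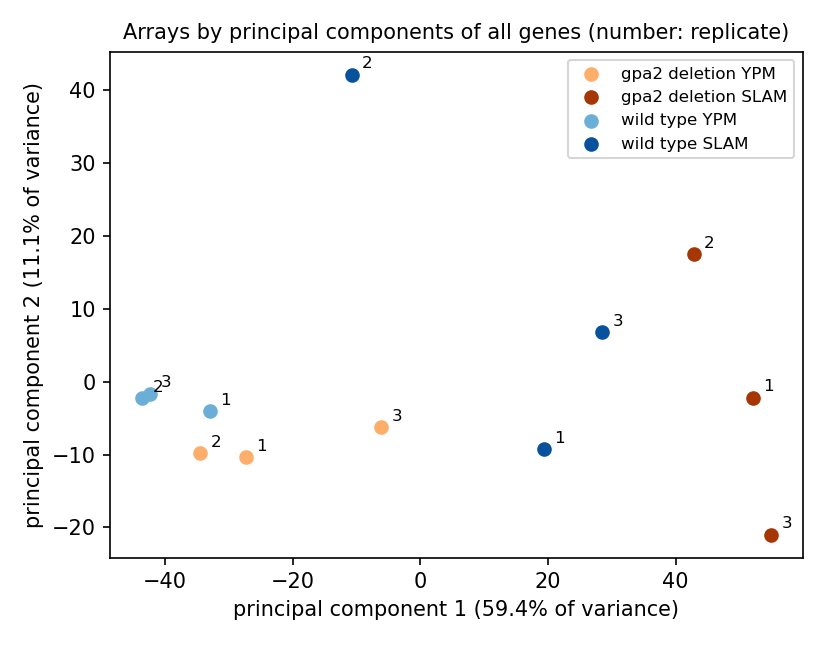
The 12 arrays on the first 2 principal components of 5656 genes, in component units. Each point is 1 array, coloured by group, with its replicate number beside it.

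In wild-type cells, genes of nitrogen scavenging were among those that rose most in SLAM, and genes of iron retention among those that fell most. DAL80, a GATA factor of nitrogen catabolite repression, rose at least 20.8-fold (log2 4.38, SE 0.65, n = 3 per group, adjusted p = 0.00472). GAP1, the general amino acid permease, rose 19.5-fold (log2 4.29, SE 0.36), and MEP2, the high-affinity ammonium permease, rose 19.0-fold (log2 4.25, SE 0.53). The cell wall mannoproteins of iron retention FIT1 (log2 -4.26, SE 1.02) and FIT2 (log2 -4.23, SE 1.10) fell 19.1-fold and 18.8-fold. Of 5656 genes, 296 were higher and 415 lower in SLAM (711, 12.6%), of which 221 and 324 changed at least 2-fold.

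The rest of the 10 largest wild-type rises were SPG4 (log2 3.99, SE 0.83), YCL048W-A (3.79, SE 0.80), the transcription factor gene NRS1 (3.53, SE 0.78), the allantoate permease gene DAL5 (3.41, SE 0.80), LEE1 (3.40, SE 0.56), the malate synthase gene MLS1 (3.35, SE 0.69) and the gluconeogenic gene PCK1 (3.29, SE 0.82). DAL5 had 2 further probe sets, at 1.61 and 3.29. DAL80, YCL048W-A and NRS1 averaged 5.35, 5.59 and 5.23 in YPM, no higher than the deleted GPA2 gene read on its highest array (5.60), so their rises are lower bounds. The other large falls were in the amino acid permease genes TAT1 (log2 -3.47, SE 0.38) and BAP3 (-3.03, SE 0.57), INA1 (-3.20, SE 0.57), the phosphate transporter gene PHO84 (-3.17, SE 0.63), VHR2 (-3.11, SE 0.30), the copper transporter gene CTR3 (-2.99, SE 0.59) and the reductase gene FRE1 (-2.97, SE 0.57). RPS22B fell by 3.39 on the log2 scale (SE 0.38), on a probe set that can share targets, so the gene behind this value is uncertain. A further RPS22B probe set, not marked as sharing targets, read -4.54, and another that can share targets read -3.88. FLO11, the cell-surface flocculin of filamentous growth, stood at log2 0.31 (SE 0.27, adjusted p = 0.468) from a high YPM mean of 13.06, and URA3 at -0.35 (SE 0.22, adjusted p = 0.287).

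Among nitrogen genes, 9 of 20 measured nitrogen catabolite repression targets rose in wild-type SLAM and none fell (12 adjusted over the list alone; median log2 1.53), and camera gave adjusted p = 1.11e-09, or adjusted p = 0.411 with an estimated correlation. Of 8 ammonium transport and assimilation genes, 2 rose, MEP2 and GDH3 (log2 1.89, SE 0.50), 3 adjusted over the list alone (camera adjusted p = 0.00632; adjusted p = 0.411 with an estimated correlation). Amino acid biosynthesis was mixed, with 7 of 42 genes higher, among them ARG1 (log2 2.64, SE 0.78), LYS1 (2.28, SE 0.58), ARG4 (2.22, SE 0.41) and ARG3 (2.07, SE 0.60), and 2 lower (7 and 2 adjusted over the list alone). Camera gave this list adjusted p = 0.277, or adjusted p = 0.695 with an estimated correlation. In sulfate assimilation and methionine synthesis, MET6 (log2 3.12, SE 0.47), MET13 (2.79, SE 0.24) and STR3 (2.62, SE 0.67) rose out of 20 genes, 10 adjusted over the list alone (median log2 1.63; camera adjusted p = 1.9e-05; adjusted p = 0.516 with an estimated correlation). Without wild-type SLAM replicate 2 the median was 0.97, and camera gave adjusted p = 0.0173, or adjusted p = 0.638 with an estimated correlation.

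Genes of the protein synthesis machinery were among those that fell in wild-type SLAM. Of 80 measured cytosolic ribosomal proteins, 37 fell and none rose (67 lower and 1 higher adjusted over the list alone), with RPL7B (log2 -2.78, SE 0.76), RPL9A (-2.45, SE 0.40), both on probe sets that can share targets, and RPL3 (-2.29, SE 0.51) after RPS22B. Camera gave adjusted p = 2.42e-19, or adjusted p = 0.411 with an estimated correlation, for this list with a median of -1.23. Among 69 ribosome biogenesis factors, 38 fell (57 adjusted over the list alone; median -1.31; camera adjusted p = 2.04e-19; adjusted p = 0.411 with an estimated correlation), including NSR1 (log2 -2.10, SE 0.63), NOP1 (-2.09, SE 0.49), PUF6 (-2.03, SE 0.42) and UTP13 (-1.93, SE 0.43). Mitochondrial ribosomal proteins fell in 32 of 67 cases, MRP4 (log2 -1.88, SE 0.39) and RSM26 (-1.69, SE 0.23) among them (49 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.15e-17; adjusted p = 0.411 with an estimated correlation). RNA polymerase I and III subunits had 6 falls among 19, with RPA49 (log2 -1.73, SE 0.44) and RPA43 (-1.66, SE 0.43) among the largest (13 adjusted over the list alone; camera adjusted p = 4.04e-06; adjusted p = 0.411 with an estimated correlation). Aminoacyl-tRNA synthetases also had 6 falls, CDC60 (log2 -1.29, SE 0.38) included, among 18 (14 adjusted over the list alone; camera adjusted p = 5.76e-07; adjusted p = 0.411 with an estimated correlation).

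Genes of autophagy, vacuolar proteolysis and stress were among those that rose in the same cells. Autophagy genes rose in 14 of 36 cases, led by ATG40 (log2 1.95, SE 0.52), ATG33 (1.64, SE 0.26), ATG8 (1.51, SE 0.31) and ATG45 (1.44, SE 0.25), and 20 passed adjusted over the list alone (camera adjusted p = 1.34e-10; adjusted p = 0.411 with an estimated correlation). Vacuolar proteases rose in 3 of 6, APE1 (log2 1.42, SE 0.41), PRB1 (1.31, SE 0.32) and PRC1 (1.04, SE 0.23), with 4 adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.411 with an estimated correlation). In the general stress response, 7 of 19 rose (9 adjusted over the list alone), CTT1 (log2 2.76, SE 0.83), DDR2 (1.86, SE 0.33), MSC1 (1.83, SE 0.34) and TFS1 (1.57, SE 0.27) among them, at camera adjusted p = 2.03e-07 and adjusted p = 0.411 with an estimated correlation. Trehalose and glycogen metabolism had 2 rises among 16, ATH1 (log2 1.29, SE 0.38) and NTH1 (0.99, SE 0.23), 2 adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.516 with an estimated correlation). MLS1, PCK1 and CAT2 (log2 2.01, SE 0.32) rose among 13 genes of gluconeogenesis and glyoxylate cycle, 3 adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.551 with an estimated correlation). Fatty acid oxidation included the rises of CTA1 (log2 2.83, SE 0.69) and POT1 (2.13, SE 0.63), 2 of 13 genes, 4 adjusted over the list alone (camera adjusted p = 8.76e-05; adjusted p = 0.411 with an estimated correlation).

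Members of nucleotide, iron and signalling lists passed too in wild-type SLAM. Iron uptake genes fell in 5 of 19 cases, ARN2 (log2 -2.87, SE 0.82) with FIT1, FIT2 and FRE1 (14 adjusted over the list alone; camera adjusted p = 7.89e-07; adjusted p = 0.411 with an estimated correlation). Purine synthesis had 5 falls among 15, including IMD4 (log2 -1.97, SE 0.55), ADE6 (-1.36, SE 0.28) and the shared-probe-set gene IMD3 (-1.44, SE 0.35), with 8 adjusted over the list alone (camera adjusted p = 0.00024; adjusted p = 0.411 with an estimated correlation). Pyrimidine synthesis and uptake was mixed, URA8 (log2 1.84, SE 0.34) and URA10 (1.70, SE 0.46) higher, FUR1 (-1.78, SE 0.36) and URA7 (-1.75, SE 0.33) lower, out of 13 (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.297; adjusted p = 0.576 with an estimated correlation). In the cAMP and protein kinase A pathway, 7 of 20 rose, RGS2 (log2 1.49, SE 0.25), YAK1 (1.10, SE 0.29) and GPA2 among them, and TPK3 fell 2.29-fold (SE 0.31 on the log2 scale). The pathway had 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.411 with an estimated correlation). Of 22 filamentous growth genes, PHD1 rose (log2 1.71, SE 0.34) and SHO1 fell (-1.09, SE 0.31), 1 and 1 adjusted over the list alone (camera adjusted p = 0.958; adjusted p = 0.975 with an estimated correlation).

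The wild-type counts of 296 and 415 became 36 and 26 without wild-type YPM replicate 2, 70 and 83 without YPM replicate 3 and 166 and 225 without YPM replicate 1. They were 155 and 288 without SLAM replicate 1, 57 and 50 without SLAM replicate 3, and 647 and 767 without SLAM replicate 2, while the 6 wild-type arrays alone gave 163 and 213, array weights 969 and 1234, and median centring 381 and 362. Of the 20 genes with the largest changes, DAL80, GAP1, MEP2, LEE1, TAT1, RPS22B, INA1 and VHR2 passed under every alternative, and the others lost the call under at least 1 of them.

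In gpa2 deletion cells, nitrogen genes were again among the largest rises in SLAM, and nucleolar and ribosomal protein genes among the largest falls. DAL80 rose at least 49.5-fold (log2 5.63, SE 0.65, n = 3 per group, adjusted p = 0.000325), the proline oxidase gene PUT1 27.8-fold (log2 4.80, SE 0.98) and MEP2 22.7-fold (log2 4.50, SE 0.53). The nucleolar protein genes NOP1 (log2 -4.03, SE 0.49) and NSR1 (-3.98, SE 0.63) fell 16.3-fold and 15.8-fold, and the ribosomal protein gene RPS26B fell 15.1-fold (log2 -3.92, SE 0.57). In all, 757 genes were higher and 835 lower in SLAM (1592, 28.1%), 500 and 662 of them by at least 2-fold.

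The other large rises in deletion cells were YCL048W-A (log2 5.05, SE 0.80), SPG4 (4.29, SE 0.83), the peroxisomal catalase gene CTA1 (4.27, SE 0.69), PHM7 (4.14, SE 0.73), GAP1 (4.14, SE 0.36), the allantoin permease gene DAL4 (4.08, SE 0.69) and DAL5 (3.95, SE 0.80), whose other probe sets read -0.10 and 2.71. The largest fall was that of BAP3 (log2 -4.10, SE 0.57). DAL80 averaged 5.00 in YPM and BAP3 4.83 in SLAM, under the highest GPA2 reading of the deletion strain (5.60), so both changes are lower bounds. The other large falls were VHR2 (log2 -3.93, SE 0.30), RPL13A (-3.79, SE 0.49), NOP56 (-3.71, SE 0.80), the hexokinase gene HXK2 (-3.63, SE 0.52), TAT1 (-3.62, SE 0.38) and RPL27A (-3.61, SE 0.40), the last on a probe set that can share targets. All 20 of these genes passed under every alternative that tested them. PHM7 and BAP3 were not tested where the dimmest genes were left out. FLO11 stood at log2 0.21 (SE 0.27, adjusted p = 0.591), URA3 at -0.40 (SE 0.22, adjusted p = 0.194) and GPA2 at -0.08 (SE 0.23, adjusted p = 0.837).

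Among protein synthesis genes in deletion cells, 78 of 80 cytosolic ribosomal proteins fell and none rose (78 adjusted over the list alone; median log2 -2.54), RPL16B (-3.54, SE 0.44) among them. Camera gave adjusted p = 8.76e-35, or adjusted p = 0.274 with an estimated correlation. Of 69 ribosome biogenesis factors, 68 fell (68 adjusted over the list alone; median -2.24; camera adjusted p = 1.29e-30; adjusted p = 0.274 with an estimated correlation), UTP13 (log2 -3.58, SE 0.43) included. RNA polymerase I and III subunits fell in 17 of 19 cases (18 adjusted over the list alone), with RPA49 (log2 -3.42, SE 0.44), RPA135 (-2.97, SE 0.36), RPA12 (-2.83, SE 0.42) and RPA43 (-2.72, SE 0.43) furthest. Camera gave this list adjusted p = 4.65e-10, and adjusted p = 0.274 with an estimated correlation. Aminoacyl-tRNA synthetases fell in 16 of 18 (17 adjusted over the list alone), FRS1 (log2 -2.38, SE 0.34), WRS1 (-2.34, SE 0.35) and CDC60 (-2.13, SE 0.38) among them (camera adjusted p = 4.65e-10; adjusted p = 0.274 with an estimated correlation). Mitochondrial ribosomal proteins had 37 falls and 1 rise among 67 (44 and 1 adjusted over the list alone), with MRP13 (log2 -1.73, SE 0.42) and MRPL49 (-1.70, SE 0.37) lowest (camera adjusted p = 4.78e-11; adjusted p = 0.536 with an estimated correlation).

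Nitrogen genes passed in deletion cells as well. Of 20 nitrogen catabolite repression targets, 14 rose and none fell (16 adjusted over the list alone; median log2 2.31; camera adjusted p = 3.42e-08; adjusted p = 0.364 with an estimated correlation). Ammonium transport and assimilation split within 8 genes, 4 rising, GLT1 (log2 2.60, SE 0.60) and GDH3 (1.60, SE 0.50) among them, while GDH1 fell by 2.12 on the log2 scale (SE 0.43). Of these 4 and 1 were called adjusted over the list alone (camera adjusted p = 0.131; adjusted p = 0.557 with an estimated correlation). Amino acid biosynthesis had 4 rises, with LEU1 (log2 2.78, SE 0.35) and CPA1 (1.75, SE 0.34), and 9 falls, with ASN2 (-2.77, SE 0.65) and ARO4 (-2.33, SE 0.29), among 42 genes (4 and 9 adjusted over the list alone; camera adjusted p = 0.194; adjusted p = 0.638 with an estimated correlation). In sulfate assimilation and methionine synthesis 8 of 20 rose (8 adjusted over the list alone), MET6 (log2 3.75, SE 0.47), MET13 (3.45, SE 0.24), STR3 (2.70, SE 0.67) and MET10 (2.58, SE 0.79) furthest. The list median was 1.51, and the camera value was adjusted p = 0.00157, or adjusted p = 0.602 with an estimated correlation. Without deletion SLAM replicate 2 the median was 0.66 and the camera call ended (adjusted p = 0.0928).

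Genes for carbon storage, fat and acetate use were among those that rose in deletion cells. Every one of 13 fatty acid oxidation genes rose (13 adjusted over the list alone; median log2 2.00), POT1 (2.85, SE 0.63), FOX2 (2.41, SE 0.52) and PXA1 (2.29, SE 0.48) included. The camera value was adjusted p = 3.59e-07, and adjusted p = 0.355 with an estimated correlation. Gluconeogenesis and glyoxylate cycle genes rose in 10 of 13 (10 adjusted over the list alone), IDP2 (log2 3.77, SE 0.86), MLS1 (3.49, SE 0.69), ACS1 (2.92, SE 0.67) and PCK1 (2.76, SE 0.82) among them (camera adjusted p = 1.29e-05; adjusted p = 0.422 with an estimated correlation). Trehalose and glycogen metabolism rose in 9 of 16 (13 adjusted over the list alone), with GLG2 (log2 2.08, SE 0.61), ATH1 (2.01, SE 0.38), GAC1 (1.40, SE 0.38) and TPS2 (1.27, SE 0.44). For these camera gave adjusted p = 3.67e-05, and adjusted p = 0.415 with an estimated correlation. The general stress response rose in 10 of 19 (14 adjusted over the list alone), with CTT1 (log2 3.53, SE 0.83), RTN2 (2.03, SE 0.37), HSP42 (1.91, SE 0.35) and MSC1 (1.90, SE 0.34). Stress genes had camera adjusted p = 4.56e-06, and adjusted p = 0.274 with an estimated correlation. Autophagy rose in 26 of 36 (29 adjusted over the list alone), with ATG39 (log2 2.78, SE 0.72), ATG40 (2.55, SE 0.52), ATG1 (2.30, SE 0.47) and ATG42 (1.81, SE 0.37). Autophagy had camera adjusted p = 2.29e-11, and adjusted p = 0.274 with an estimated correlation. The vacuolar proteases PRB1 (log2 1.27, SE 0.32) and PRC1 (1.16, SE 0.23) rose, 2 of 6 (3 adjusted over the list alone; camera adjusted p = 0.0139; adjusted p = 0.415 with an estimated correlation).

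Purine synthesis fell in 10 of 15 deletion-strain cases and rose in 1 (14 and 1 adjusted over the list alone), IMD4 (log2 -2.88, SE 0.55), ADE2 (-1.94, SE 0.36), ADE4 (-1.78, SE 0.40) and the shared-probe-set gene IMD3 (-2.69, SE 0.35) lowest. Purine genes had camera adjusted p = 3.32e-06, and adjusted p = 0.274 with an estimated correlation. Pyrimidine synthesis and uptake had 6 falls, FUR1 (log2 -3.19, SE 0.36), URA7 (-2.94, SE 0.33) and FUI1 (-2.22, SE 0.44) among them, and 2 rises, URA10 (2.25, SE 0.46) included, of 13 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0139; adjusted p = 0.274 with an estimated correlation). Iron uptake genes fell in 4 of 19, FIT2 (log2 -3.42, SE 1.10), FRE1 (-2.79, SE 0.57), FTR1 (-2.14, SE 0.60) and SIT1 (-1.81, SE 0.62), with 9 adjusted over the list alone (camera adjusted p = 0.00103; adjusted p = 0.587 with an estimated correlation). The cAMP and protein kinase A pathway had 7 rises, GPB2 (log2 1.57, SE 0.36), YAK1 (1.48, SE 0.29) and TPK2 (1.02, SE 0.22) among them, and 1 fall, TPK3 (-1.55, SE 0.31), of 20 (7 and 1 adjusted over the list alone; camera adjusted p = 0.102; adjusted p = 0.415 with an estimated correlation). Filamentous growth had STE11 higher (log2 0.74, SE 0.25) and STE20 lower (-0.68, SE 0.20) of 22, neither adjusted over the list alone (camera adjusted p = 0.974; adjusted p = 0.99 with an estimated correlation). Its median was 0.10, its mean -0.00 and its camera direction upward.

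The deletion-strain counts of 757 and 835 became 411 and 609 without deletion YPM replicate 1, 402 and 543 without YPM replicate 2, 432 and 598 without SLAM replicate 1, and 1552 and 1350 with array weights. Without deletion YPM replicate 3 the iron uptake genes had 15 falls and a median of -2.82, the mitochondrial ribosomal proteins 15 falls, and camera gave pyrimidine synthesis and uptake adjusted p = 0.0505. Without deletion SLAM replicate 2 it gave vacuolar proteases adjusted p = 0.0630.

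**Figure D3:**
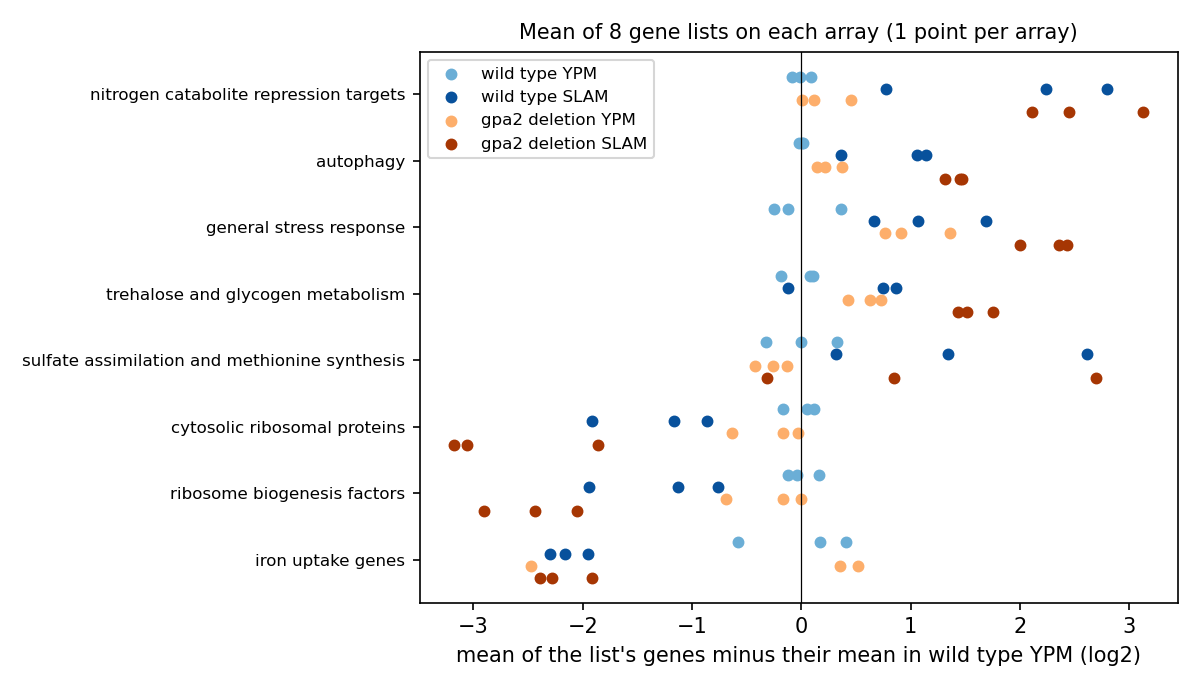
Mean log2 expression of 8 gene lists in each array, minus the mean of the wild-type YPM arrays. Each point is 1 of the 12 arrays, grouped by strain and medium.

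In YPM, GPA2 was the only gene that passed between the strains. It was at least 23.7-fold lower in the deletion strain (log2 -4.57, SE 0.23, n = 3 per group). limma gave 0 genes higher and 1 lower, with 119 higher and 101 lower at unadjusted p < 0.05. These were 220 of 5656 genes, fewer than 5%. The error was estimated over the arrays of both media. The median gene SD was 0.208 and 0.227 in YPM (wild type and deletion), against 0.387 and 0.340 in SLAM. The YPM p values may therefore be too large, so this count cannot be read against the 5% that chance gives. The strains did not overlap in 1088 genes (19.2%), more than chance alone gives. The YPM arrays alone also gave 0 higher and 1 lower, with fewer arrays to estimate the error. Array weights gave 29 and 5, all probe sets 1 higher, and fry called 0 gene lists. Values that did not pass in listed genes were PIR3 at log2 2.39 (SE 0.55), the glucose-regulated transporter gene HXT2 at -2.12 (SE 0.83) and DAN1 at 1.88 (SE 0.53). Others were SSE2 at 1.51 (SE 0.48), MSC1 at 1.46 (SE 0.34), GAC1 at 1.23 (SE 0.38), HXK2 at -1.16 (SE 0.52), TFS1 at 1.09 (SE 0.27) and PGM2 at 1.07 (SE 0.30), with adjusted p = 0.994 each. FLO11 stood at log2 0.01 (SE 0.27) and URA3 at -0.39 (SE 0.22).

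By camera at the preset correlation, the general stress response was higher in deletion cells in YPM. All 19 of its members had positive differences (median log2 1.02), 8 were higher adjusted over the list alone, and camera gave adjusted p = 1.45e-19, or adjusted p = 0.0850 with an estimated correlation. The list averaged 0.91, 0.76 and 1.36 above the wild-type YPM mean on the deletion arrays, and 0.37, -0.25 and -0.12 on the wild-type arrays (exact two-sided p = 0.1, the smallest possible with 3 against 3). Trehalose and glycogen metabolism had positive differences in 16 of 16 genes (median log2 0.58), none passing adjusted over the list alone, at camera adjusted p = 2.15e-12 and adjusted p = 0.331 with an estimated correlation. Autophagy (median log2 0.27; camera adjusted p = 1.61e-05; adjusted p = 0.543 with an estimated correlation) and vacuolar proteases (0.56; camera adjusted p = 0.00122; adjusted p = 0.543 with an estimated correlation) were also higher by camera. Mitochondrial ribosomal proteins were lower (median log2 -0.39; camera adjusted p = 9.58e-09; adjusted p = 0.877 with an estimated correlation). Without deletion YPM replicate 3 the median for mitochondrial ribosomal proteins was -0.63 (adjusted p = 4.46e-27; adjusted p = 0.298 with an estimated correlation). No member of these lists passed over all genes.

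Further camera calls in YPM depended on deletion YPM replicate 3. With it, cytosolic ribosomal proteins had a median of log2 -0.25 (camera adjusted p = 0.0023), ribosome biogenesis factors -0.30 (0.00122), gluconeogenesis and glyoxylate cycle 0.37 (0.0314), fatty acid oxidation 0.45 (0.00122) and nitrogen catabolite repression targets 0.20 (0.0104), each at adjusted p = 0.877 with an estimated correlation. Without it these were -0.09 (adjusted p = 0.79), -0.04 (0.904), -0.26 (0.795), 0.08 (0.292) and 0.12 (0.0782), and iron uptake genes went from -0.50 (adjusted p = 0.112) to 0.38 (2.41e-07; adjusted p = 0.298 with an estimated correlation).

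In SLAM, the genes that passed between strains included ribosomal and nucleolar protein genes, lower in deletion cells, and reserve-carbohydrate genes, higher in them. In each case they were a minority of their lists. The numbers in the sample titles run lower on every deletion array than on every wild-type array. A processing order that follows them could not be told apart from strain in either medium. The omega-class glutathione transferase gene GTO1 was 6.11-fold higher (log2 2.61, SE 0.29, n = 3 per group, adjusted p = 0.00344), and PHM7 was 9.04-fold higher (log2 3.18, SE 0.73). SNU13, a protein of the small nucleolar RNA particles and spliceosome, was 5.70-fold lower (log2 -2.51, SE 0.47), FSH1 5.55-fold lower (-2.47, SE 0.38) and HXK2 5.32-fold lower (-2.41, SE 0.52). In all, 61 genes were higher and 98 lower (159, 2.81%), GPA2 among the latter. The error was estimated over all 12 arrays, so these calls rest in part on the YPM arrays, whose median gene SD was lower.

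The other leading rises in deletion cells in SLAM were GIP2 (log2 2.39, SE 0.51), ALD3 (2.37, SE 0.49), the small nucleolar RNA SNR67 (2.36, SE 0.35), RTN2 (2.34, SE 0.37), GND2 (2.29, SE 0.49), PNS1 (2.07, SE 0.50), RTC3 (1.87, SE 0.31) and the trehalose phosphatase gene TPS2 (1.83, SE 0.44). How well amplification from a poly-T primer captured SNR67 was not tested. The other leading falls were RPL6B (log2 -2.41, SE 0.47), NOP1 (-2.30, SE 0.49) and the RNA polymerase I gene RPA12 (-2.26, SE 0.42). TPO2 (-2.99, SE 0.65), RPL27A (-2.31, SE 0.40) and RPL17B (-2.28, SE 0.51) also fell, on probe sets that can share targets, so these genes are uncertain. FLO11 stood at log2 -0.08 (SE 0.27, adjusted p = 0.898) and URA3 at -0.44 (SE 0.22, adjusted p = 0.258).

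Of 80 cytosolic ribosomal proteins, 19 were lower in deletion cells in SLAM, RPL13A (log2 -2.08, SE 0.49) among them (70 adjusted over the list alone; median -1.47; camera adjusted p = 6.4e-30; adjusted p = 0.349 with an estimated correlation). Ribosome biogenesis factors were lower in 13 of 69 cases, BRX1 (log2 -1.94, SE 0.34), EBP2 (-1.96, SE 0.47) and the shared-probe-set gene NOP58 (-2.20, SE 0.36) included, with 49 adjusted over the list alone (camera adjusted p = 2.03e-22; adjusted p = 0.349 with an estimated correlation). RNA polymerase I and III subunits were lower in 5 of 19, with RPA49 (log2 -2.02, SE 0.44), RPC19 (-1.60, SE 0.34) and RPA135 (-1.50, SE 0.36), 14 adjusted over the list alone (camera adjusted p = 3.36e-09; adjusted p = 0.349 with an estimated correlation). The aminoacyl-tRNA synthetases WRS1 (log2 -1.86, SE 0.35), FRS1 (-1.64, SE 0.34) and MES1 (-1.29, SE 0.26) were lower, 3 of 18 (4 adjusted over the list alone; camera adjusted p = 9.94e-06; adjusted p = 0.558 with an estimated correlation). Pyrimidine synthesis and uptake was lower in FUR1 (log2 -1.81, SE 0.36), URA7 (-1.78, SE 0.33) and URA6 (-1.70, SE 0.32), 3 of 13 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0256; adjusted p = 0.349 with an estimated correlation). Amino acid biosynthesis was lower in HIS7 (log2 -1.29, SE 0.28) and THR1 (-0.80, SE 0.19), 2 of 42 (2 adjusted over the list alone; camera adjusted p = 5.66e-05; adjusted p = 0.349 with an estimated correlation). GDH1 was lower too (-1.79, SE 0.43).

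Trehalose and glycogen metabolism was higher in deletion cells in SLAM in 5 of 16 genes, GAC1 (log2 1.61, SE 0.38), GDB1 (1.35, SE 0.32), GLG1 (1.31, SE 0.29), TSL1 (0.95, SE 0.19) and TPS2, with 13 adjusted over the list alone (camera adjusted p = 4.41e-10; adjusted p = 0.349 with an estimated correlation). The general stress response was higher in 3 of 19, ALD3, RTN2 and MSC1 (log2 1.52, SE 0.34) (12 adjusted over the list alone; camera adjusted p = 2.21e-08; adjusted p = 0.349 with an estimated correlation). In fatty acid oxidation no gene passed over all genes and 10 of 13 were higher adjusted over the list alone, FOX2 at log2 2.06 (SE 0.52) and FAA2 at 1.47 (SE 0.37) nearest (camera adjusted p = 2.51e-07; adjusted p = 0.349 with an estimated correlation). Gluconeogenesis and glyoxylate cycle likewise had none over all genes and 6 of 13 adjusted over the list alone, with ACS1 at log2 2.07 (SE 0.67; camera adjusted p = 4.92e-05; adjusted p = 0.607 with an estimated correlation). Autophagy had 1 of 36, ATG4 (log2 0.75, SE 0.18; 1 adjusted over the list alone; camera adjusted p = 7.98e-07; adjusted p = 0.349 with an estimated correlation). Nitrogen catabolite repression targets had 1 of 20, UGA1 (log2 1.49, SE 0.33; 3 adjusted over the list alone; camera adjusted p = 0.00588; adjusted p = 0.781 with an estimated correlation). In the cAMP and protein kinase A pathway BCY1 was higher (log2 0.86, SE 0.20) and RGS2 (-1.33, SE 0.25) and GPA2 lower. In this list 5 and 3 were called adjusted over the list alone, and the median of 0.23 and mean of -0.08 differed in sign (camera adjusted p = 0.554; adjusted p = 0.826 with an estimated correlation). The list includes GPA2, the deleted gene, whose difference of log2 -5.53 enters the mean, the count of lower genes and the camera value. Among filamentous growth genes MGA1 was higher (log2 1.54, SE 0.33) and PHD1 lower (-1.75, SE 0.34), 1 and 1 adjusted over the list alone, with a median of 0.01, a mean of -0.03 and camera adjusted p = 0.838, or adjusted p = 0.948 with an estimated correlation.

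The SLAM strain counts of 61 and 98 fell to 7 and 13 without wild-type SLAM replicate 2, 22 and 29, 3 and 9, and 3 and 7 without wild-type YPM replicates 1, 2 and 3, 6 and 8, and 9 and 26 without deletion YPM replicates 1 and 2, and 1 and 3, and 28 and 52 without deletion SLAM replicates 1 and 2. They were 140 and 51 without wild-type SLAM replicate 1, 83 and 302 without wild-type SLAM replicate 3, 55 and 149 without deletion SLAM replicate 3, and 0 and 1 on the 6 SLAM arrays alone, 38 and 55 with a floor, 13 and 28 over all probe sets, 83 and 77 with median centring, and 203 and 297 with array weights. Without wild-type SLAM replicate 2 no cytosolic ribosomal proteins passed over all genes (median log2 -1.24; camera adjusted p = 3.41e-24; adjusted p = 0.425 with an estimated correlation), nitrogen catabolite repression targets had a median of 0.00 (adjusted p = 0.497), and of all named genes only GPA2 kept its call under every alternative. Without deletion SLAM replicate 2 camera gave nitrogen catabolite repression targets adjusted p = 0.186. It then called sulfate assimilation and methionine synthesis lower (median -1.15, adjusted p = 0.00216; adjusted p = 0.778 with an estimated correlation).

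The 2 strains' responses to SLAM were alike in direction across genes. Over 5656 genes, which are not independent replicates, the log2 changes correlated at Pearson 0.851 and Spearman 0.831, with an SD of 0.769 in the wild type, wild-type SLAM replicate 2 included, and 0.989 in the deletion strain. Both strains had DAL80, GAP1 and MEP2 higher and TAT1, BAP3 and VHR2 lower. Genes higher in both numbered 238, where 39.6 would be shared if the lists were independent, genes lower in both 350, where 61.3 would be, and genes called in opposite directions 0. Both sets of calls used the same error estimate for a gene, so they were not independent and these baselines may be too low. Of 1715 genes called in either strain, 1694 had the same sign in both.

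**Figure D4:**
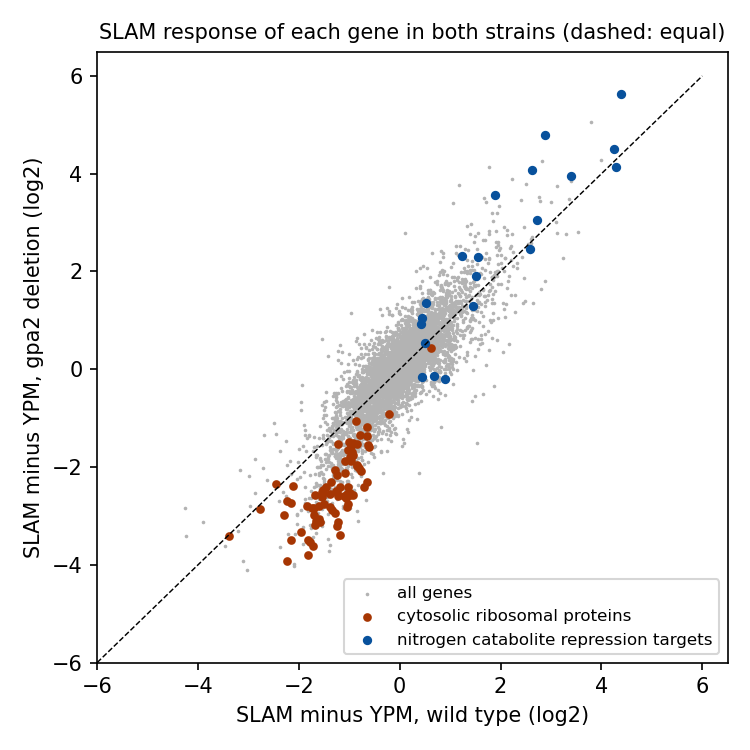
Log2 change from YPM to SLAM in the wild type (horizontal) and the gpa2 deletion (vertical) for 5656 genes, 1 point per gene. Cytosolic ribosomal protein genes are red, nitrogen catabolite repression targets blue, and the dashed line marks equal change.

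No gene's response to SLAM differed between strains after adjustment. GTO1 had the smallest adjusted p, at log2 2.69 (SE 0.42, n = 3 per group, adjusted p = 0.173). GPA2 stood at log2 -0.97 (SE 0.32, adjusted p = 0.980), FLO11 at -0.09 (SE 0.38) and URA3 at -0.04 (SE 0.31). limma called 0 higher and 0 lower, with 98 and 130 at unadjusted p < 0.05, fry called 0 gene lists, and array weights gave 1 and 1. In simulated data the same test recovered 9% of genes changed by log2 1 and 55% of those changed by log2 2.

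Camera called 13 of 39 gene lists in this comparison, and none of the calls remained with an estimated correlation. Cytosolic ribosomal proteins had a median of log2 -1.13 (camera adjusted p = 1.07e-33; adjusted p = 0.594 with an estimated correlation), with RPL6B at -2.20 (SE 0.67) and the shared-probe-set gene RPL27A at -1.89 (SE 0.56), neither passing. Ribosome biogenesis factors had -0.79 (camera adjusted p = 3.51e-23), with GAR1 at -1.50 (SE 0.42) and the shared-probe-set gene NOP58 at -2.03 (SE 0.51). An exact test that swapped strain labels within each medium gave two-sided p = 0.215 for the ribosomal proteins over 200 splits. Among all lists the smallest exact two-sided p = 0.035 was that of pyrimidine synthesis and uptake, and adjusted over the lists both came to 0.919. Pyrimidine synthesis and uptake (median -0.58; camera adjusted p = 0.000288; adjusted p = 0.290 with an estimated correlation) had FUR1 at log2 -1.42 (SE 0.51) and URA7 at -1.19 (SE 0.47). Gluconeogenesis and glyoxylate cycle had a median of 1.10 (camera adjusted p = 0.00183), with IDP2 at log2 2.60 (SE 1.22) and ADR1 at 1.21 (SE 0.48), and fatty acid oxidation 0.72 (camera adjusted p = 9.18e-05), with FOX2 at 1.59 (SE 0.74). Among filamentous growth and cAMP and protein kinase A pathway genes, PHD1 stood at log2 -1.62 (SE 0.48) and RGS2 at -0.85 (SE 0.36), neither passing. Without wild-type SLAM replicate 2 the camera calls ended for gluconeogenesis and glyoxylate cycle (median 0.59, adjusted p = 0.074), trehalose and glycogen metabolism (0.23, adjusted p = 0.374) and autophagy (0.09, adjusted p = 0.62). Other lists were then called, namely mitochondrial ribosomal proteins (0.34, adjusted p = 3.86e-05), proteasome (0.23, 0.000814), thiamine and pyridoxine synthesis (-0.40, 0.00899), cell wall proteins and cell wall integrity (-0.37, 0.0330) and haploid cell markers (-0.19, 0.0443). With an estimated correlation no list was called in that setting (smallest adjusted p = 0.150). Without deletion SLAM replicate 2 the call ended for mitochondrially encoded genes (0.39, adjusted p = 0.0944). It began for G1/S cell cycle genes (-0.74, adjusted p = 2.26e-05), sulfate assimilation and methionine synthesis (-0.90, 0.00227), meiosis and sporulation markers (0.33, 0.0175), daughter cell separation genes (0.45, 0.0345) and cell wall proteins and cell wall integrity (-0.33, 0.0345). With an estimated correlation none was called there either (smallest adjusted p = 0.544).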

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

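The regroupings of arrays, the exact test of strain labels and the estimated correlation were set beforehand, and the other tests in this part were chosen after the result was seen. Quantile normalization was planned as an alternative, but its use here as a test of the ribosomal protein result was chosen afterwards. A difference between the strains' SLAM responses, by camera at the preset correlation, marked 13 gene lists for a closer look. Their median log2 differences (deletion minus wild type) were -0.56 for amino acid biosynthesis, -1.13 for cytosolic ribosomal proteins, -0.79 for ribosome biogenesis factors, -0.82 for RNA polymerase I and III subunits, -0.63 for aminoacyl-tRNA synthetases, 1.10 for gluconeogenesis and glyoxylate cycle, 0.34 for respiratory chain and ATP synthase, 0.72 for fatty acid oxidation, 0.29 for trehalose and glycogen metabolism, 0.28 for autophagy, -0.58 for pyrimidine synthesis and uptake, -0.53 for purine synthesis and 0.54 for mitochondrially encoded genes. The smallest adjusted p among these with an estimated correlation was 0.290, for pyrimidine synthesis and uptake. A signal in probe sets outside the gene tests was marked as well: of 2771 without 1 gene symbol, 118 (4.26%) passed in the wild-type SLAM response, 69 higher and 49 lower, and 206 (7.43%) in the deletion strain, 105 higher and 101 lower, against 8.92% and 22.8% of the named probe sets.

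The arrays of each comparison were also regrouped into 3 and 3 in all 10 ways. As many genes as in the real grouping passed in 1 of 10 in the wild-type SLAM response (711, highest other 1), in 1 of 10 in the deletion-strain response (1592, highest other 0), in 1 of 10 between strains in YPM (1, highest other 0) and in 1 of 10 between strains in SLAM (159, highest other 1), too few groupings for a value under 0.05. For the difference of responses the real count was 0, so all 100 regroupings drawn out of 200 had to give as many (highest other 1), and this leaves the question of chance open.

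Wild-type SLAM replicate 2 stood apart from the other wild-type SLAM arrays. Its RNA as a mixture of YPM and SLAM RNA was argued against by genes called at least 2-fold changed in deletion cells. Matching the 500 that rose would take 72% of YPM RNA (70% and 75% against single arrays). Matching the 662 that fell would take 27% (15% and 34%). An earlier form of that test, which counted genes outside the range of the other arrays (198 on this array, 132 on wild-type SLAM replicate 3, 194 on deletion SLAM replicate 3), separated too little and was replaced after its result was seen. Degraded RNA was argued against by a 3'-minus-5' difference of 1.21, where another array had 1.29, and a swapped strain label by GPA2 at 10.999, where the highest deletion array had 5.60. What set this culture or array apart stays open, and no biological explanation was tested.

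General stress genes were higher in the deletion strain than in the wild type in YPM by camera at the preset correlation. With an estimated correlation camera gave adjusted p = 0.0850, and fry called 0 lists. The exact two-sided permutation test gave p = 0.1, and no member passed over all genes. Deletion YPM replicate 3 alone as the source was argued against by a median of 0.79 without it, and nitrogen shortage or SLAM RNA in those cultures by the nitrogen catabolite repression targets, which reached 10.1% of their wild-type SLAM response where the stress genes reached 89.0%. An order of processing that follows the strain stays open, since the title numbers change strain only 1 time. The deletion itself could raise these genes. Because the title numbers follow the strain, order and genotype were not separable in YPM or in SLAM.

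By camera at the preset correlation, ribosomal protein genes fell further in SLAM in the deletion strain than in the wild type. With an estimated correlation no list was called in this comparison. fry called 0 lists, and no gene passed over all genes. Wild-type SLAM replicate 2 alone was argued against by a difference of -0.91 without it. After quantile normalization the difference was -1.25. The array medians were already close (7.34 to 7.51), and quantile normalization also assumes alike distributions on all arrays. It therefore could not decide whether the normalization between arrays gave this difference. Chance assignment of the strain labels stays open, with an exact two-sided p of 0.215 over 200 splits. A stronger shutdown of ribosome synthesis without GPA2 could also give this difference, and these arrays leave it undecided.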

How the results depend on the processing

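Leaving out both arrays that stood apart, leaving out each of them or deletion SLAM replicate 2 alone for the gene lists, and array weights were chosen after seeing the data. The other alternatives were set beforehand. Counts are given as higher and lower. A floor gave 38 and 55 between strains in SLAM. All probe sets gave 1 higher between strains in YPM and 13 and 28 in SLAM. Only the 6 arrays of a comparison gave 163 and 213 in the wild-type SLAM response and 0 and 1 between strains in SLAM. Those fits had fewer arrays to estimate the error. Between strains in SLAM the fit also lost the YPM arrays, whose median gene SD was lower (0.208 and 0.227, against 0.387 and 0.340 in SLAM). These effects were not told apart. Requiring 2-fold gave 500 higher in the deletion-strain response. Adjusted p < 0.01 gave 43 and 27 in the wild-type response, 337 and 483 in the deletion strain's and 1 and 1 between strains in SLAM. Leaving out both arrays that stood apart gave 690 and 835 in the wild-type response, 1 higher between strains in YPM (DAN1), 34 and 38 in SLAM, and 2 lower (YMC2 and AAH1) for the difference of responses. Between strains in YPM the camera direction of ribosome biogenesis factors turned (median -0.0446). The medians turned to -0.26 for gluconeogenesis and glyoxylate cycle and 0.38 for iron uptake genes, and the iron uptake median for the difference of responses to -0.28. Array weights gave 969 and 1234, 1552 and 1350, 29 and 5, 203 and 297, and 1 and 1 in the 5 comparisons. The lowest weight was 0.172 (wild-type SLAM replicate 2) and the highest 3.29 (wild-type YPM replicate 3). Deletion SLAM replicate 3 had a weight of 0.337, under that of deletion YPM replicate 3 (0.559). It was not among the arrays counted as standing apart, and no gene list was rerun without it. With 1 array left out, which also lowers the number of arrays, the wild-type response ranged from 36 to 647 higher and 26 to 767 lower (lowest without YPM replicate 2, highest without SLAM replicate 2), and the deletion strain's from 402 to 976 higher and 543 to 979 lower. Between strains the range was 0 to 1 higher in YPM, and 1 to 140 higher and 3 to 302 lower in SLAM; for the difference of responses it was 0 to 1 higher and 0 to 2 lower. The similarity of the SLAM responses of the 2 strains ranged from 0.788 (without wild-type SLAM replicate 1) to 0.868 (without wild-type SLAM replicate 2), and a change of 0.05 counted as moved. Between strains in YPM the median ranged from -0.26 to 0.37 for gluconeogenesis and glyoxylate cycle, -0.21 to 0.0540 for the tricarboxylic acid cycle and -0.50 to 0.38 for iron uptake genes, in each case turning without deletion YPM replicate 3. The mitochondrial ribosomal proteins ranged from -0.38 (without deletion SLAM replicate 2) to -0.0710 between strains in SLAM (without wild-type SLAM replicate 2), where camera turned upward, and the iron uptake genes from -0.57 to 0.42 for the difference of responses. Unless given here, the cause was not tested. A change of sign in a value that was not called was not counted as turned. Quantile normalization (318 and 422; 762 and 812; 82 and 126) kept every direction, as did the variance trend for the followed genes, with no list run under it. Median centring gave 381 and 362, 843 and 795, and 83 and 77. Of the genes followed under the alternatives, 18 of 96, 85 of 130 and 3 of 49 kept their side of the threshold wherever they were tested in the 2 SLAM responses and between strains in SLAM. Between strains in YPM and for the difference of responses only GPA2, URA3 and FLO11 were followed, and they kept theirs. No followed gene turned. Of 39 lists, 18, 13, 17, 18 and 15 kept theirs in the 5 comparisons. All of these were lists without a call at the preset correlation, since over all 12 arrays none was called with an estimated correlation. Without wild-type SLAM replicate 2 autophagy passed with an estimated correlation in both SLAM responses (adjusted p = 0.0358 and 0.0355). GPA2 has 1 probe set, so another could not be tried. The number of arrays limits precision, and without detection calls signal near background could not be told from absence. No paired analysis was run, because nothing in the sources used here says that a culture of 1 group belongs with a culture of another.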

Other observations

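Members of further gene groups passed between media. The amino acid permeases induced by external amino acids, a set chosen after the values were seen, fell in 5 of 10 cases in wild-type SLAM, with TAT2 (log2 -2.32, SE 0.25), GNP1 (-2.40, SE 0.44) and BAP2 (-1.90, SE 0.43) beside TAT1 and BAP3. In deletion cells 5 of 10 fell and AGP3 rose (1.34, SE 0.31). The copper uptake genes, also chosen after, fell in 4 of 4 and 3 of 4, with the transporter gene CTR1 at log2 -2.83 in both (SE 0.40). In another such set, 60 small nuclear and nucleolar RNA genes, 8 fell in wild-type and 10 in deletion cells, against 415 and 835 of all 5656 genes. The wild-type ones included SNR63 (log2 -2.03, SE 0.29) and SNR68 (-1.84, SE 0.53). None of these added sets had a list test. How well amplification from a poly-T primer captured small nuclear and nucleolar RNAs was not tested either. Phosphate starvation genes went both ways in the wild type, with PHO8 (log2 2.25, SE 0.27), PHM8 (2.05, SE 0.48) and PHM6 (1.52, SE 0.41) higher and PHO84 lower. The counts were 3 and 2 of 12 (3 and 2 adjusted over the list alone; camera adjusted p = 0.297; adjusted p = 0.658 with an estimated correlation). Deletion cells had 3 and 1 (4 and 1 alone; camera adjusted p = 0.102; adjusted p = 0.538 with an estimated correlation), SPL2 (log2 1.12, SE 0.22) included. Haploid cell markers rose in these diploid cells in 3 of 21 wild-type cases, SAG1 (log2 1.14, SE 0.26), FUS1 (1.10, SE 0.24) and the shared-probe-set gene MFA1 (1.82, SE 0.45). The count was 3 adjusted over the list alone (camera adjusted p = 0.00083; adjusted p = 0.411 with an estimated correlation). In deletion cells 2 rose (2 alone; camera adjusted p = 0.058; adjusted p = 0.616 with an estimated correlation). RNA was amplified from a poly-T primer, and its capture of mitochondrially encoded transcripts was not tested. The mitochondrially encoded genes COX2 (log2 2.11, SE 0.51) and COX3 (1.88, SE 0.49) rose in the wild type, 2 of 8 (3 higher and 3 lower adjusted over the list alone). Their median was -0.53, their mean 0.13 and the camera value downward (adjusted p = 0.883; adjusted p = 0.969 with an estimated correlation). COB rose in deletion cells (log2 1.36, SE 0.34; 1 alone; camera adjusted p = 0.194; adjusted p = 0.602 with an estimated correlation).

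In glycolysis and fermentation HXK2 fell in the wild type (log2 -2.38, SE 0.52), 1 of 19 (1 adjusted over the list alone; median -0.01, mean 0.01; camera adjusted p = 0.883; adjusted p = 0.969 with an estimated correlation). In deletion cells PDC6 rose (3.39, SE 0.66) and HXK2 and the shared-probe-set gene ENO2 (-1.12, SE 0.26) fell (1 and 2 alone; camera adjusted p = 0.94; adjusted p = 0.99 with an estimated correlation). Hexose transporters and sensors had RGT2 higher in the wild type (log2 1.09, SE 0.24), 1 of 15 (1 alone; camera adjusted p = 0.195; adjusted p = 0.63 with an estimated correlation). Deletion cells had RGT2 (1.37, SE 0.24) and HXT5 (2.75, SE 0.78) higher (2 alone; camera adjusted p = 0.194; adjusted p = 0.616 with an estimated correlation). For maltose and alpha-glucoside use the wild type had none of 7, IMA5 at log2 -0.58 (SE 0.19) and MAL13 at 0.43 (SE 0.26) nearest (camera adjusted p = 0.689; adjusted p = 0.869 with an estimated correlation). MAL33 rose in deletion cells (0.83, SE 0.26; 0 alone; camera adjusted p = 0.302; adjusted p = 0.655 with an estimated correlation). The tricarboxylic acid cycle had none of 15 in the wild type, with SDH2 at log2 1.36 (SE 0.52) and IDH2 at -0.87 (SE 0.34; camera adjusted p = 0.195; adjusted p = 0.695 with an estimated correlation). Deletion cells had 5 higher, SDH3 (2.83-fold, SE 0.50) and SDH1 (log2 1.10, SE 0.36) included (6 alone; camera adjusted p = 0.0261; adjusted p = 0.587 with an estimated correlation). The respiratory chain and ATP synthase had none of 32 in the wild type (camera adjusted p = 0.441; adjusted p = 0.914 with an estimated correlation). CYC7 (log2 1.98, SE 0.58) and QCR8 (0.83, SE 0.27) rose in deletion cells (0 alone; camera adjusted p = 0.00352; adjusted p = 0.638 with an estimated correlation). Between strains in SLAM the tricarboxylic acid cycle and the respiratory chain and ATP synthase had camera adjusted p = 0.0256 each, or adjusted p = 0.781 and 0.833 with an estimated correlation. Without deletion SLAM replicate 2 these camera calls ended (adjusted p = 0.100 for the tricarboxylic acid cycle and 0.186 for the respiratory chain and ATP synthase). So did that of the tricarboxylic acid cycle in the deletion strain's response (adjusted p = 0.0755).

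Heat shock chaperones rose in 3 of 16 wild-type cases, SSE2 (log2 1.86, SE 0.48), SIS1 (0.72, SE 0.22) and the shared-probe-set gene HSP82 (1.34, SE 0.29). There were 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0597; adjusted p = 0.604 with an estimated correlation). In deletion cells 3 rose and SSA2 fell (-2.00, SE 0.45; 3 and 1 alone; camera adjusted p = 0.289; adjusted p = 0.703 with an estimated correlation). Oxidative stress genes had CCP1 higher in the wild type (log2 2.17, SE 0.48), 1 of 13 (1 alone; camera adjusted p = 0.292; adjusted p = 0.547 with an estimated correlation). Deletion cells had 2 higher, CCP1 (1.91, SE 0.48) included, and TRR1 lower (-1.36, SE 0.47; 1 and 0 alone; camera adjusted p = 0.269; adjusted p = 0.585 with an estimated correlation). Cell wall proteins and cell wall integrity genes had PIR3 higher in the wild type (log2 2.46, SE 0.55), 1 of 17 (1 alone; camera adjusted p = 0.471; adjusted p = 0.764 with an estimated correlation). Deletion cells had 2 higher and 4 lower, TIR1 (-2.09, SE 0.66), DAN1 (-1.57, SE 0.53) and TIR3 (-1.29, SE 0.37) among the latter (2 and 4 alone; camera adjusted p = 0.92; adjusted p = 0.99 with an estimated correlation). The proteasome had none of 34 in the wild type (camera adjusted p = 0.297; adjusted p = 0.869 with an estimated correlation). Its regulator RPN4 (log2 1.15, SE 0.28) and PRE3 (0.55, SE 0.18) rose in deletion cells (1 alone; camera adjusted p = 0.0456; adjusted p = 0.699 with an estimated correlation). RPN1 was higher in deletion than wild-type cells in SLAM (0.96, SE 0.22; 1 alone; camera adjusted p = 0.0452; adjusted p = 0.833 with an estimated correlation). Both proteasome calls ended without deletion SLAM replicate 2 (adjusted p = 0.312 and 0.499). Ergosterol synthesis had none of 24 in the wild type (camera adjusted p = 0.353; adjusted p = 0.764 with an estimated correlation). In deletion cells 4 rose, ERG9 (log2 0.96, SE 0.20) included, and ERG4 fell (-1.73, SE 0.43; 3 and 1 alone; camera adjusted p = 0.687; adjusted p = 0.923 with an estimated correlation).

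G1/S cell cycle genes had none of 14 in the wild type, RNR1 at log2 -1.82 (SE 0.74) and CDC9 at -0.68 (SE 0.29; camera adjusted p = 0.0823; adjusted p = 0.695 with an estimated correlation). RNR1 (-2.89, SE 0.74), POL1 (-1.06, SE 0.30) and CLN2 (-1.01, SE 0.33) fell in deletion cells (3 alone; camera adjusted p = 0.00834; adjusted p = 0.601 with an estimated correlation). G2/M cell cycle genes had none of 8 in either strain (camera adjusted p = 0.476 and 0.988; adjusted p = 0.869 and 0.99 with an estimated correlation), with CLB1 at log2 -1.04 (SE 0.72) and -0.90. Daughter cell separation genes had none of 9 in the wild type (median -0.06, mean -0.09, camera upward at adjusted p = 0.883; adjusted p = 0.969 with an estimated correlation). CTS1 rose in deletion cells (log2 0.94, SE 0.29; 0 alone; camera adjusted p = 0.233; adjusted p = 0.703 with an estimated correlation). Histones had 3 measured genes, none passing, with HTB1 at log2 0.23 (SE 0.27) and 0.45, and were too few for a list test. Meiosis and sporulation markers had none of 17 in the wild type (camera adjusted p = 0.136; adjusted p = 0.617 with an estimated correlation). In deletion cells 4 were higher, SGA1 (log2 1.86, SE 0.49) and SMK1 (1.08, SE 0.26) included (3 alone; camera adjusted p = 0.028; adjusted p = 0.536 with an estimated correlation). Zinc uptake genes had none of 6 in either strain (camera adjusted p = 0.477 and 0.988; adjusted p = 0.695 and 0.99 with an estimated correlation), ZPS1 standing at log2 1.59 (SE 0.75) and 1.54. In deletion cells their median of 0.03 was positive and the camera value downward. Thiamine and pyridoxine synthesis had THI6 higher in the wild type (log2 0.60, SE 0.17), 1 of 9 (3 alone; camera adjusted p = 0.00531; adjusted p = 0.411 with an estimated correlation). None rose in deletion cells, THI4 at 0.56 (SE 0.27; camera adjusted p = 0.241; adjusted p = 0.663 with an estimated correlation).

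Between strains in YPM, camera at the preset correlation also called cell wall proteins and cell wall integrity higher (median log2 0.18; 2 alone; adjusted p = 0.000118; adjusted p = 0.331 with an estimated correlation). Further calls included heat shock chaperones (0.13; adjusted p = 0.017), glycolysis and fermentation (0.09; adjusted p = 0.0347) and thiamine and pyridoxine synthesis (0.25; adjusted p = 0.0104), each at adjusted p = 0.877 with an estimated correlation, with no member past the threshold over all genes. Not all of the 12 and 4 lists called between strains in YPM, or the 9 and 8 in SLAM, are described. None was called with an estimated correlation. The arrays that stood apart did so in more groups. In wild-type SLAM replicate 2 daughter cell separation genes lay at -1.70 from the mean of its group's other arrays (9 of 9 lower than both), G2/M cell cycle genes at -1.23 (8 of 8 lower) and mitochondrially encoded genes at 0.78 (8 of 8 higher). In deletion YPM replicate 3 the respiratory chain and ATP synthase lay at 0.80 (31 of 32 higher than both), mitochondrial ribosomal proteins at 0.72 (65 of 67 higher) and iron uptake genes at -2.91 (19 of 19 lower).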
